A study of Homo sapiens with 6 samples.

How the data were processed

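RNA sequencing was analysed from 6 libraries of Ker-CT cells, a human keratinocyte line immortalised with telomerase and CDK4. Per the labels, 3 libraries came from cells that received siRNA against KMT2C (siKMT2C) and 3 from cells that received negative-control siRNA (siNC). Every culture was treated for 24 h with the M5 cocktail, which holds TNF-α, IL-1α, IL-17A, IL-22 and oncostatin M at 10 ng/ml apiece, per the labels' protocols. There was no unstimulated sample among those used here, so the effect of the cytokines themselves was not measured. Per the labels' protocols, RNA was extracted with a Qiagen column kit and libraries were made with a SMARTer mRNA kit. The siRNA sequences, their number and the transfection schedule were not given in the sources used here, nor was strand information.

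The authors deposited one table with whole-number read counts per gene, and the same table held FPKM values (fragments per kilobase of transcript, scaled to library depth), per the file headers. Per the submitters' processing notes, the tools were CASAVA 1.8 and TopHat2 2.0.6. The same notes name the mouse build mm10, while the gene identifiers in the table are human Ensembl identifiers, so that build was not used. The counting program, the annotation and the human build were not given in the sources used here. The deposited FPKM values were checked against the counts: in 8586 genes the implied gene length was the same in every library, with a largest relative deviation of 2.8e-06. The FPKM columns were the counts rescaled, and all tests used the counts.

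The table had 58302 gene entries, of which 28494 had a count of 0 in every library. GENCODE 29 (GRCh38) held 58039 of the identifiers (99.55%), and 42667 had a gene symbol. Coordinates, gene types, coding sequences and 3′ UTRs come from GENCODE 29 on GRCh38 and are not coordinates of the authors' build. Reads that pseudogenes, close paralogs, overlapping genes or antisense genes share with another gene may have been split in counting, and levels of such genes are uncertain.

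Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with default settings, libraries were scaled by the trimmed mean of M-values (TMM), and siKMT2C was compared with siNC by a robust quasi-likelihood F test. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and a gene was called at an adjusted p under 0.05. A standard error is the absolute log2 fold change divided by the square root of F. CPM, counts scaled to library size, used TMM-scaled library sizes. The test left 15063 genes.

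Gene lists were tested with camera in limma 3.58.1 on voom log2 values, two-sided, with a preset inter-gene correlation of 0.01, adjusted over the 35 lists with at least 5 tested members. An estimated correlation and fry were alternatives; 95% limits of an estimated correlation treated its variance inflation as a chi-square with 4 residual degrees of freedom. Before the data were examined, 39 lists were fixed for keratinocyte biology, cytokine signalling, the KMT2 complexes, cell cycle, stress, lipid synthesis, RNA interference, RNA quality and markers of other cell types. Of 881 list entries, 1 matched no entry of the table and 740 were tested. KMT2C was left out of the test of its own list.

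The rule for named genes was also fixed before the data were examined. It takes KMT2C and its family and complex members, then the 12 largest rises and the 12 largest falls. Those 24 came from called genes with a symbol, a mean log2 CPM of at least 1 and no overlap between groups. Of each list, it takes at most 4 members with the smallest p, whether or not they were called. A few genes that the rule takes are not reported here.

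The settings tried were median-ratio size factors (RLE), library size alone, no filter, a CPM of at least 1 in 3 libraries, DESeq2 1.42.0, limma-voom, a replicate block, a 1.5-fold minimum (glmTreat) and leaving out each library in turn. A loess correction for transcript GC content and length (span 0.3), alone, with the block or with an estimated correlation, was added after seeing the data. A list test without genes carrying either of 2 sequence motifs was added likewise. For those motifs, all 16384 possible 7-mers were scanned in the 3′ UTRs and coding sequences of 12137 tested genes with a 3′ UTR of at least 50 bases. Each 7-mer's presence was regressed on the rank-normalised signed root of F, given region length, GC content and mean expression, which yields a z value per 7-mer. 7-mers in fewer than 30 genes were left out. Scans and figures used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9, and permutation tests across genes used 100000 resamples.

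The edgeR step was tested on simulated data for this comparison, with 14822 genes in the step. It recovered 17.9% of genes changed 1.5-fold, 58.2% of those changed 2-fold and 98.5% of those changed 4-fold, all in the right direction. All planted changes were in genes with a mean CPM over 1, and the libraries' GC trends were left out. Recovery at lower levels was not measured. Of 125 calls, 8 were false and 1 was in a further list of 30 genes moved 1.5-fold together. A simulation carried the libraries' GC and length trends with their mean difference between groups taken out, and no group effect. It gave 0 edgeR calls with the correction and 0 without it. It cannot show whether a trend that differs between the groups makes calls. In the 7-mer scan, a planted 7-mer ranked 1, and shuffled changes gave z values from -4.06 to 3.7. Shuffling removes expression shared between genes, so that range does not hold for regrouped libraries, whose z values reached further.

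Total counts per library were 14409277 to 17539519. The biological coefficient of variation was 0.217, the median standard error of a log2 fold change was 0.20, and the smallest called change was a log2 size of 0.56. Replicates within a group differed by more than sampling noise, with a chi-square per degree of freedom of 17.3 to 74.5, so none was counted as a repeat of another. The labels number the replicates and do not say that they came from separate cultures, so p-values measure the spread between these samples, which may be technical.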

Results

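Expression was measured in Ker-CT keratinocytes held under the psoriasis-type M5 cytokines for 24 h, in 3 libraries with KMT2C siRNA and 3 with control siRNA. Per the series title, the comparison asks how depletion of KMT2C, a histone H3 lysine 4 methyltransferase, alters gene expression in such cells. The siKMT2C libraries held 16414777, 15921870 and 16401355 counts, and the siNC libraries 17326044, 14409277 and 17539519. The 10 most abundant genes took 8.01% to 8.79% of counts, and mitochondrial transcripts 4.83% to 6.65%.

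KMT2C (ENSG00000055609, chromosome 7, 152134922 to 152436005, GRCh38) was lower in all 3 siKMT2C libraries. Its level was 32.0, 30.8 and 27.3 CPM there, against 87.9, 82.0 and 72.6 CPM in siNC. KMT2C fell by 1.43 on the log2 scale (SE 0.14, n = 3 per group, edgeR adjusted p = 0.00786), which left 37.1% of the control level (95% interval 29.7% to 46.5%). The exact two-sided permutation test of KMT2C gave p = 0.1, the smallest that 3 against 3 libraries allow. Its 3′ UTR carries 2 copies of the 7-mer GTATAAA, and TCGGAGA occurs 1 time in its coding sequence or 3′ UTR. The KMT2C call was lost when some libraries were left out: its edgeR adjusted p was 0.0634 without siKMT2C replicate 1, 0.0507 without siKMT2C replicate 2 and 0.0593 without siNC replicate 2.

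**Figure D1:**
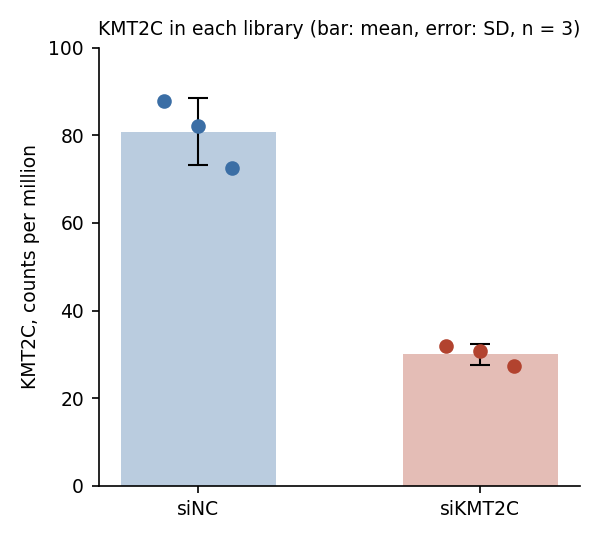
KMT2C in CPM (vertical axis) in siNC and siKMT2C libraries; points are libraries, bars group means and error bars SD (n = 3). The siKMT2C libraries lie between 27.3 and 32.0 and the siNC libraries between 72.6 and 87.9.

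None of the 16 other tested members of the KMT2 family and its COMPASS-like complexes passed the edgeR test, over all genes or adjusted over the list alone. The smallest p-values were those of SETD1B (log2 fold change -0.54, SE 0.20), PAGR1 (0.52, SE 0.20), NCOA6 (-0.31, SE 0.12) and RBBP5 (0.28, SE 0.14), with edgeR adjusted p from 0.225 to 0.351. The paralogs KMT2A, KMT2B and KMT2D had log2 fold changes of -0.24 (SE 0.12), -0.30 (SE 0.21) and -0.34 (SE 0.23). SETD1A (-0.14), WDR5 (0.14), ASH2L (-0.08), DPY30 (0.02), KDM6A (0.11), PAXIP1 (0.01), HCFC1 (-0.30), MEN1 (-0.20) and CXXC1 (-0.22) were not called either. The sign for SETD1A, DPY30, KDM6A, PAXIP1 and MEN1 differed under some settings. As a set, the list gave a camera adjusted p of 0.371, and 0.765 with an estimated correlation.

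Across all genes, 104 rose and 122 fell in siKMT2C. Of the called protein-coding genes with a symbol, a mean log2 CPM of at least 1 and no overlap between groups, the largest rises were in the cationic amino acid transporter SLC7A2 (2.51, SE 0.18), the tropomyosin TPM4 (2.20, SE 0.13), the collagen gene COL6A3 (1.94, SE 0.25) and the cyclin-dependent kinase CDK14 (1.92, SE 0.17), in log2 units. TPM4 went from 139.9 ± 13.4 to 643.3 ± 57.2 CPM (SD, n = 3). By the same limits the largest falls were in the TGF-β co-receptor TGFBR3 (-3.40, SE 0.21), the transcription factor MAF (-2.88, SE 0.27), the pro-apoptotic gene BMF (-2.86, SE 0.26) and the cytokine IL24 (-2.78, SE 0.26). TGFBR3 went from 15.9 ± 2.54 to 1.49 ± 0.0962 CPM, and IL24 from 18.3 ± 4.66 to 2.66 ± 0.497 CPM.

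Further large rises were in HABP4 (1.89), the nucleolar gene NOLC1 (1.81), ZNF616 (1.77), the lysine methyltransferase SETD7 (1.65), the pentraxin PTX3 (1.56) and SHLD2 (1.45). The pseudogenes ZNF702P (2.67) and TPM4P3 (1.96) also rose, and reads shared with ZNF genes or with TPM4 leave their levels uncertain. Further large falls were in the sodium channel subunit SCNN1A (-2.28), the aquaporin AQP3 (-2.28), INPP5J (-2.16), RAB7B (-2.14), the tight junction genes CGN (-2.11) and CLDN23 (-1.94), SNRNP25 (-2.10) and the carboxypeptidase CPA4 (-2.10). Among these 24 genes the edgeR adjusted p ran from 0.00171 for TPM4 and TGFBR3 to 0.0488 for AQP3. TGFBR3 lies on chromosome 1 (91680343 to 91906335), TPM4 on chromosome 19 (16067021 to 16103005) and SLC7A2 on chromosome 8 (17497088 to 17570573), all GRCh38.

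TCGGAGA occurs in the coding sequence or 3′ UTR of SLC7A2, TPM4, CDK14, HABP4, NOLC1, ZNF616, SETD7 and SHLD2, and of the fallen MAF and SCNN1A. GTATAAA occurs in the 3′ UTR of the fallen TGFBR3 (4 copies), CGN (1) and SNRNP25 (1), and of the risen ZNF616 (1). COL6A3, PTX3, BMF, IL24, AQP3, INPP5J, RAB7B, CPA4 and CLDN23 carry neither.

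**Figure D2:**
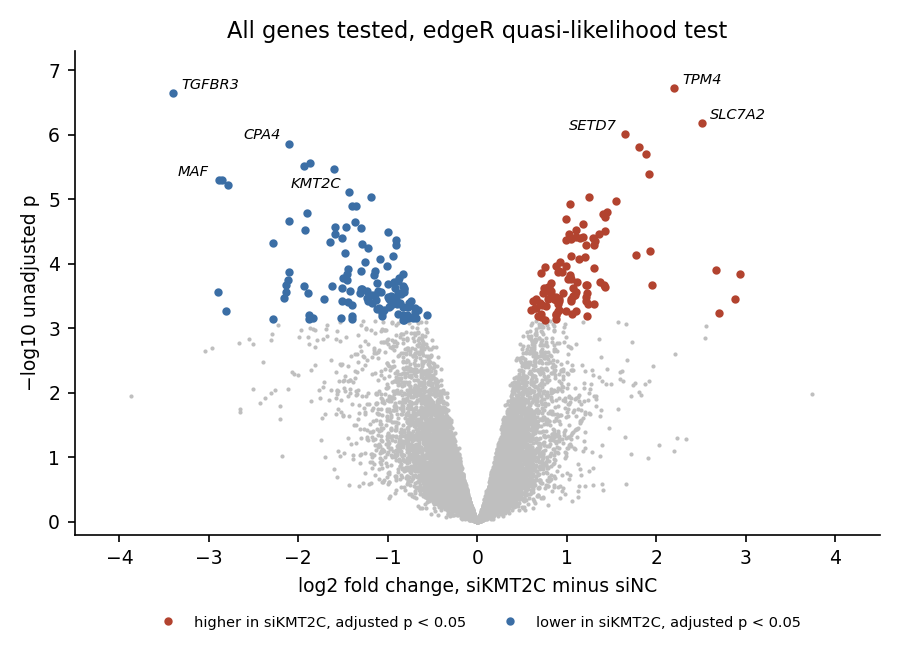
Each point is a gene, with its log2 fold change (siKMT2C minus siNC, horizontal axis) and the −log10 of its unadjusted edgeR p (vertical axis). The 104 genes that rose and the 122 that fell are coloured, and named genes include KMT2C at -1.43.

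**Figure D3:**
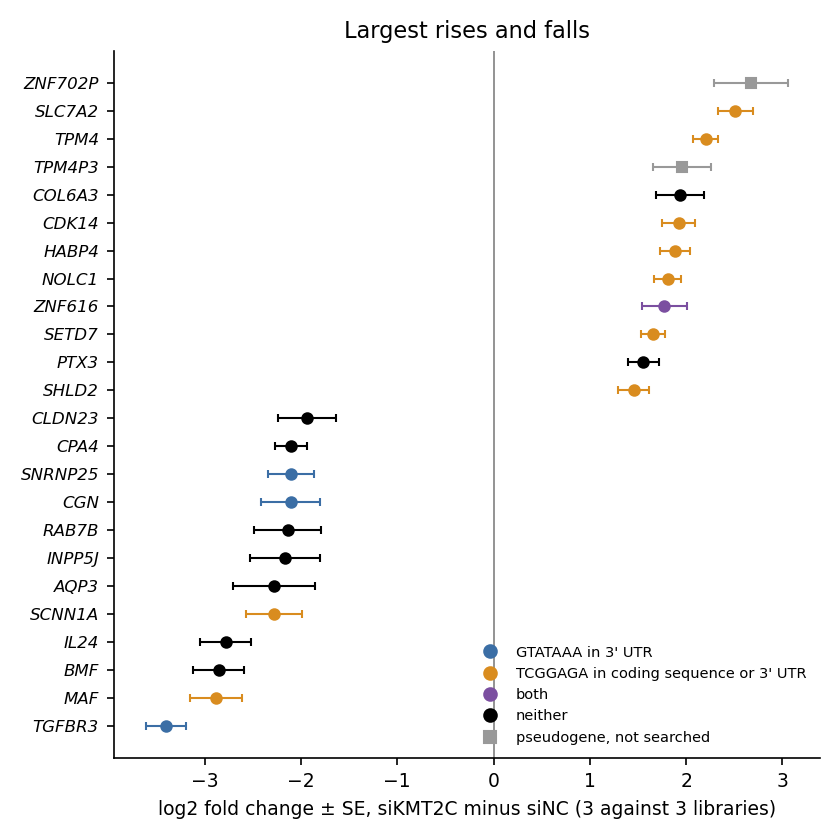
The 12 largest rises and 12 largest falls by the fixed rule, as log2 fold change with SE (3 against 3 libraries); colours mark genes carrying GTATAAA in the 3′ UTR, TCGGAGA in the coding sequence or 3′ UTR, both or neither, and squares mark pseudogenes. Values run from -3.40 for TGFBR3 to 2.67 for ZNF702P.

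Of 15063 genes tested, 226 changed (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), and 138 of them by 2-fold or more. Of the risen genes 96 were protein-coding, as were 117 of the fallen ones, and 9 of the 226 were pseudogenes. The groups did not overlap in 3636 genes (24.1%, against 10% by chance). The count of changed genes was 20, 19 and 34 without siKMT2C replicate 1, 2 and 3, and 52, 16 and 620 without siNC replicate 1, 2 and 3. It was 799 with DESeq2, 1358 after correction for GC content and length, and 18 for changes beyond 1.5-fold (glmTreat).

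Genes of DNA replication rose together in siKMT2C. All 38 tested members of the S phase list had a positive log2 fold change, with a median of 0.40 (camera adjusted p = 3.36e-11, and adjusted p = 0.0392 with an estimated correlation). The licensing factor CDC6 rose by 0.90 (SE 0.13, edgeR adjusted p = 0.0263) and the helicase component CDC45 by 0.88 (SE 0.16, edgeR adjusted p = 0.0452). GINS1 (0.72, SE 0.14) and MCM10 (0.66, SE 0.15) were not called over all genes. Over all genes 2 members rose, and 8 did when adjusted over the list alone. The G2/M list was also higher as a set, with 30 of 35 members positive and a median of 0.21 (camera adjusted p = 0.0024, and adjusted p = 0.487 with an estimated correlation). No G2/M member was called over all genes, and 1 was adjusted over the list alone: the phosphatase CDC25B (-1.04, SE 0.21), which was lower. BUB1B (0.40), AURKB (0.51) and KIF2C (0.36) had positive values. Without siNC replicate 3 the G2/M list was not called (camera adjusted p = 0.0988).

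The unfolded protein response list rose as a set, with 21 of 22 members positive and a median of 0.47 (camera adjusted p = 8.38e-09, and adjusted p = 0.127 with an estimated correlation). The disulfide isomerase PDIA4 rose from 782.2 to 1772 mean CPM (1.18, SE 0.14, edgeR adjusted p = 0.0128), and CRELD2 rose by 1.05 (SE 0.14, edgeR adjusted p = 0.0188). These 2 were called over all genes, and 11 members rose when adjusted over the list alone, the chaperone CALR (0.64, SE 0.13) and MANF (0.76, SE 0.16) among them. The cholesterol synthesis list was higher as a set, with 21 of 25 members positive and a median of 0.29 (camera adjusted p = 0.000996, and adjusted p = 0.121 with an estimated correlation). None of its members was called over all genes (edgeR, all genes tested: 2548 at an unadjusted p under 0.05). Adjusted over the list alone 4 rose, FDPS (0.72), FDFT1 (0.44) and HMGCS1 (0.87) among them.

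Several epidermal lists were lower as sets. In the desmosome and adhesion list 18 of 20 members were negative, with a median of -0.32 (camera adjusted p = 0.000273, and adjusted p = 0.121 with an estimated correlation). CGN and the claudin CLDN1 (-1.17, SE 0.20, edgeR adjusted p = 0.0366) fell over all genes. Adjusted over the list alone, 4 fell and 1 rose, PERP (0.62, SE 0.13); CLDN4, at 0.370 against 2.38 mean CPM, was among the fallen. CGN and CLDN1 each carry 1 GTATAAA in the 3′ UTR, and without genes carrying either 7-mer this list was not called (camera adjusted p = 0.112).

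In the epidermal transcription factor list 17 of 19 members were negative, with a median of -0.25 (camera adjusted p = 0.000202, and adjusted p = 0.121 with an estimated correlation). MAF fell over all genes, and 5 members fell adjusted over the list alone. Among these 5 were HES1 (-1.05, SE 0.20), NOTCH2 (-0.57, SE 0.11, 1 GTATAAA) and GRHL3 (-1.79, SE 0.38, at 0.746 against 2.62 mean CPM). In the epidermal lipid barrier list the lipid transporter ABCA12 (-1.51, SE 0.19, edgeR adjusted p = 0.0135), NIPAL4 (-1.30, SE 0.15, edgeR adjusted p = 0.0131) and the elongase ELOVL7 (-1.52, SE 0.24, edgeR adjusted p = 0.0319; 1 GTATAAA) fell. With ELOVL4 (-0.73, SE 0.14; 1 GTATAAA), 4 fell adjusted over the list alone. The other members lay nearer 0, with 8 of 13 negative in all and a median of -0.05 (camera adjusted p = 0.026, and adjusted p = 0.511 with an estimated correlation). This call was lost without siNC replicate 1 (camera adjusted p = 0.155) and without genes carrying either 7-mer (camera adjusted p = 0.18).

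Interferon-stimulated genes were lower as a set, with 32 of 37 members negative and a median of -0.36 (camera adjusted p = 1.45e-06, and adjusted p = 0.487 with an estimated correlation). The mean over members of log2 CPM, centred per gene over the 6 libraries, was -0.297, -0.313 and 0.029 in siKMT2C replicates 1 to 3 and 0.326, 0.244 and 0.01 in siNC replicates 1 to 3, so the shift came from replicates 1 and 2 of both groups and the third replicates did not show it. No member was called over all genes, and 5 fell adjusted over the list alone, among them CMPK2 (-1.16, SE 0.26), IRF1 (-0.59, SE 0.14), MX2 (-0.83, SE 0.21) and DTX3L (-0.52, SE 0.13). In the RNA interference list 9 of 12 members were negative, with a median of -0.36 (camera adjusted p = 0.0133, and adjusted p = 0.227 with an estimated correlation). TNRC6A, a partner of the Argonaute proteins, fell by 0.82 (SE 0.13, edgeR adjusted p = 0.0328). Adjusted over the list alone 3 fell, TNRC6A, DICER1 (-0.95, SE 0.20) and AGO2 (-0.52, SE 0.12), and DROSHA rose (0.49, SE 0.12). TNRC6A, DICER1 and AGO2 each carry 1 GTATAAA, and this list was not called without genes carrying either 7-mer (camera adjusted p = 0.799) or after GC and length correction (camera adjusted p = 0.0827).

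**Figure D4:**
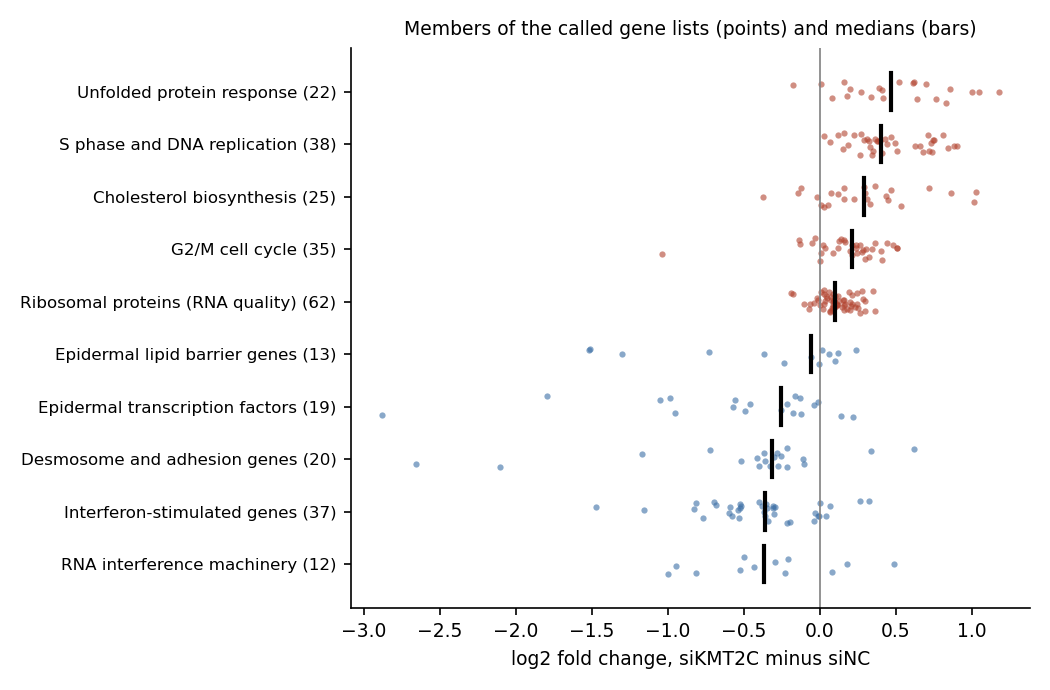
Points are tested members of the 10 called lists (number of members in brackets), with their log2 fold change (siKMT2C minus siNC) on the horizontal axis, and black bars are medians. Medians run from -0.36 in the RNA interference and interferon lists to 0.47 in the unfolded protein response list.

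Single inflammatory mediators moved in both directions, and their lists showed no shift in a shared direction. A fry test without regard to direction, which most lists passed, gave adjusted p of 7.44e-05 (chemokines) and 0.000171 (cytokines). The neutrophil chemokine CXCL1 rose by 0.90 (SE 0.16, edgeR adjusted p = 0.037), from 8.01 to 14.95 mean CPM. CXCL16 (-0.71, SE 0.18) and CCL20 (-0.74, SE 0.20; 1 GTATAAA) fell adjusted over the list alone only, and CXCL3 (0.73, SE 0.30) was not called. The chemokine list had 9 tested members, a median of -0.08 and a mean of 0.01 (camera adjusted p = 0.828, direction up). Among 17 cytokines, IL24 fell over all genes. Adjusted over the list alone, IL24 and IL1B (-0.54, SE 0.13) fell and TSLP (1.00, SE 0.21) and IL12A (1.68, SE 0.40) rose. IL12A was at a low level, 1.06 against 0.332 mean CPM in siNC. The list's median was 0.06 and its mean -0.02 (camera adjusted p = 0.828, direction up).

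In the inflammasome list NLRP3 rose by 1.22 (SE 0.23, edgeR adjusted p = 0.0464) and carries 3 TCGGAGA, and IL1B fell adjusted over the list alone. CASP4 (0.33) and NLRP10 (0.63) were not called (camera adjusted p = 0.34). Of 5 tested antimicrobial genes only LCN2 (1.36, SE 0.29) was called, adjusted over the list alone, and SLPI (-0.45), SERPINB3 (-0.37) and RNASE7 (0.13) were not (camera adjusted p = 0.828). Several genes often used as markers of the M5 response were near 0 and not tested: the 6 libraries together held 42 counts of S100A8, 68 of PI3, 35 of IL6, 8 of IL36G and 0 of S100A7 and DEFB4A.

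The receptor and adaptor list of the M5 cytokines had no called member in the edgeR test, over all genes or adjusted over the list alone. Its smallest p-values were those of IL22RA1 (-0.90, SE 0.24), STAT3 (0.40, SE 0.12), RIPK1 (-0.42, SE 0.12) and OSMR (-0.45, SE 0.14), and 15 of 21 members were negative (camera adjusted p = 0.123, and 0.025 with no filter). No NF-κB feedback target was called either, with IER3 (-0.41), TNFAIP3 (-0.30), IRAK2 (0.33) and BIRC3 (-0.56) foremost (camera adjusted p = 0.585). In the STAT3 target list none passed over all genes and 5 did adjusted over the list alone, MYC (1.76, SE 0.49; 33.2 ± 25.8 against 9.81 ± 1.49 CPM, SD, n = 3) and STAT3 up and HIF1A (-0.68, SE 0.17; 1 GTATAAA), OSMR and CCND1 (-0.38, SE 0.12) down (camera adjusted p = 0.343). For antigen presentation NLRC5 (-0.80, SE 0.18) was the only call adjusted over the list alone, with PSMB8 (0.38) and HLA-F (-0.54) not called (camera adjusted p = 0.52).

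The growth factor HBEGF rose by 1.03 (SE 0.12, edgeR adjusted p = 0.0135; 1 TCGGAGA). Adjusted over the EGFR list alone 4 rose and 5 fell, among them TGFA (0.58; 1 GTATAAA), EGFR (-0.46; 1 GTATAAA) and DUSP6 (-0.45; 2 GTATAAA), with a median of -0.03 and a mean of 0.02 (camera adjusted p = 0.828, direction down). In the matrix list the matricellular gene CCN2 rose by 1.07 (SE 0.17, edgeR adjusted p = 0.0319). Adjusted over the list alone 3 rose, CCN2 and CCN1 (0.71, SE 0.16) among them, and ITGAV fell (-0.70, SE 0.14; 3 GTATAAA and 1 TCGGAGA; camera adjusted p = 0.371). In the TGF-β list no member was called over all genes and 2 rose and 4 fell adjusted over the list alone, FST (0.54), BAMBI (0.96), ID1 (-0.63) and SMAD3 (-0.50; 1 GTATAAA) among them (camera adjusted p = 0.204). In the WNT list WNT7A (0.86) rose and LRP6 (-0.62; 4 GTATAAA and 1 TCGGAGA) and TCF7L2 (-0.75; 3 GTATAAA) fell adjusted over the list alone, and WNT5A (-0.45; 1 TCGGAGA) was not called (camera adjusted p = 0.136).

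Of the apoptosis regulators BMF fell over all genes. CASP9 (-1.01, SE 0.25; 1 GTATAAA) fell adjusted over the list alone and CFLAR (0.43) was not called; the list's median was 0.04 and its mean -0.04 (camera adjusted p = 0.704, direction up). Of the p53 targets TP53INP1 fell by 0.85 (SE 0.14, edgeR adjusted p = 0.0335), MDM2 (-0.54) fell adjusted over the list alone, and XPC (0.44; 1 GTATAAA) and CDKN1A (-0.37) were not called (camera adjusted p = 0.828). Of the NRF2 targets the malic enzyme ME1 rose by 1.30 (SE 0.17, edgeR adjusted p = 0.0146) and the ferritin heavy chain FTH1 fell by 0.91 (SE 0.11, edgeR adjusted p = 0.0137), and FTH1 has pseudogenes that can share its reads. Adjusted over the list alone 2 rose, ME1 and GCLM (0.61; 1 GTATAAA), and 3 fell, HMOX1 (-0.77) among them; the list's median was 0.02 and its mean -0.01 (camera adjusted p = 0.828, direction up).

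In the ATF4 list the lipoprotein receptor VLDLR fell by 1.30 (SE 0.21, edgeR adjusted p = 0.032), PSAT1 (0.46) rose adjusted over the list alone, and ASNS (0.55) and MTHFD2 (0.33) were not called. Its median was -0.03 and its mean -0.02 with camera direction up (adjusted p = 0.632). The hypoxia and glycolysis list had no call over all genes or adjusted over the list alone in the edgeR test, with SLC2A1 (-0.59), LDHA (-0.56; 1 GTATAAA), ENO2 (-0.77) and ADM (-0.89) foremost. That list lay just short of the threshold (camera adjusted p = 0.0518) and passed it in several alternative settings, at 0.0174 with no filter. Immediate early genes had 1 call adjusted over the list alone, FOSL2 (-0.85, SE 0.17; 2 GTATAAA and 1 TCGGAGA), with DUSP1 (-0.49) and FOSL1 (0.55) not called; the median was -0.09 and the mean 0.05 (camera adjusted p = 0.828, direction down). Of the chromatin regulators NSD1 (-0.61; 1 GTATAAA) and TET2 (-0.71; 2 GTATAAA) fell adjusted over the list alone, and HDAC1 (0.51) and TET1 (-1.42) were not called (camera adjusted p = 0.218).

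Keratin and differentiation lists were not called. The hyperproliferation keratins KRT17 (-0.33), KRT16 (-0.51), KRT6B (-0.33) and KRT6A (-0.08) showed no call (camera adjusted p = 0.204), with KRT6A at 3638 against 3852 mean CPM; KRT6A had a positive value without siNC replicate 3 (0.04). Of the basal genes COL17A1 (0.72, SE 0.16) rose and ITGA6 (-0.51; 1 GTATAAA), DST (-0.66; 1 GTATAAA) and ITGA3 (-0.57) were among the 4 that fell adjusted over the list alone (camera adjusted p = 0.18). Of 12 tested terminal differentiation genes CASP14 (-2.31, SE 0.49, at 0.350 against 1.76 mean CPM) and LYPD3 (-0.83, SE 0.20) fell adjusted over the list alone. ECM1 (-0.48) and SPRR1B (-1.04) were not called (camera adjusted p = 0.218). The hyperproliferation list was called without siKMT2C replicate 3 (0.0141) and without siNC replicate 2 (0.0447). The basal list was called without siKMT2C replicate 3 (0.0437) and without siNC replicate 1 (0.0378), and the terminal differentiation list without siKMT2C replicate 3 (0.048), all camera adjusted p.

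Signs of RNA quality and of other cells were measured alongside. Ribosomal protein genes were slightly higher, with 54 of 62 members positive and a median of 0.10 (camera adjusted p = 0.00716, and adjusted p = 0.132 with an estimated correlation), and no call after GC and length correction (camera adjusted p = 0.417) or without genes carrying either 7-mer (camera adjusted p = 0.0557). RPS12 (0.36), RPL27 (0.30), RPL9 (0.29) and RPS27A (0.28) had the smallest p, and no member was called over all genes or adjusted over the list alone. The mitochondrial list gave a camera adjusted p of 0.771, with MT-ND6 (-0.32), MT-ND3 (0.19), MT-CYB (-0.22) and MT-ND5 (-0.14) not called, and 0.0428 (lower) after GC and length correction and 0.0487 (lower) without siNC replicate 3. KCNQ1OT1 (0.29), MALAT1 (0.17) and NEAT1 (0.09), RNAs retained in the nucleus, were not called. The libraries differed in GC content within groups: the Spearman correlation across genes of a library's deviation from its group mean with transcript GC was -0.065, -0.448 and 0.48 in siKMT2C and -0.609, -0.35 and 0.688 in siNC. A trend lay between the groups as well: the log2 fold change had a Spearman correlation of -0.141 with transcript GC and -0.152 with transcript length.

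Fibroblast markers moved apart, with COL6A3 up and DCN (-1.57, SE 0.32) and COL1A1 (-0.77, SE 0.19) down adjusted over the list alone and POSTN (0.50) not called; the median was -0.09 and the mean 0.07 (camera adjusted p = 0.828, direction up). The endothelial marker KDR fell by 1.59 (SE 0.19, edgeR adjusted p = 0.0135; 1 TCGGAGA) from 9.67 to 3.21 mean CPM. The immune marker CD14 (-2.23, SE 0.43, at 0.209 against 1.00 mean CPM) fell adjusted over the list alone and CD68 (0.20) was not called. The melanocyte markers MITF (-0.82; 1 GTATAAA), MLANA (0.43) and PMEL (-0.26) were not called. The nuclear-retained, melanocyte, immune and endothelial lists had 3, 3, 2 and 1 tested members and were not tested as sets.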

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

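The GC and length correction and the list test without genes carrying either 7-mer were chosen after the results were seen; the other settings were planned. With RLE factors, library size alone, no filter, a CPM minimum of 1 and limma-voom the count of changed genes stayed within 1.5 times of 226 (214 to 310). DESeq2 called 799 (368 up, 431 down), 225 of them shared with the 226 in direction. A 1.5-fold minimum (glmTreat) left 18 (7 up, 11 down), since it tests against a larger change. GC and length correction gave 1358 (699 up, 659 down) and shared 225. Leaving out each library gave 16 to 620 changed genes, 6 to 262 up and 10 to 358 down; the 620 came without siNC replicate 3 and shared 220 of the 226. The replicate numbers are not said to mark a shared day, and same-numbered deviations correlated at 0.019, 0.107 and 0.389, so they were not taken as pairs; siKMT2C replicate 2 correlated better with siNC replicate 1 (0.318). A replicate block gave 968 changed genes (456 up, 512 down), all 226 among them, and with GC and length correction 1334 (715 up, 619 down). The block alone also called the M5 receptor and adaptor list (camera adjusted p = 0.0391) and the hypoxia list (camera adjusted p = 0.0371).

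KMT2C stayed lower in every setting that gives its value (log2 -1.51 to -1.26); its value without each library was -1.51 to -1.36. None of the 24 genes of largest change turned direction under any setting; 11 to 24 of them passed the threshold with a library left out. Lists called were 1 with an estimated correlation, 1 with GC correction and an estimated correlation, 6 without genes carrying either 7-mer, 9 with fry and 8 to 14 otherwise; fry lost the interferon, lipid barrier and G2/M lists and gained the M5 receptor and adaptor list (0.0494) and the matrix list (0.0468).

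Direction turned only for genes and lists past the threshold in neither setting, and the cause was not tested. By library size alone DPY30 had -0.0100 and PAXIP1 -0.0198. After GC and length correction SETD1A had 0.0380 and DPY30 -0.133, and with the replicate block as well 0.0371 and -0.127. With each library left out DPY30 ran from -0.0765 to 0.124, PAXIP1 from -0.0667 to 0.108, KDM6A from -0.0501 to 0.228, SETD1A from -0.300 to 0.0846, MEN1 from -0.308 to 0.0304, PMEL from -0.505 to 0.0646 and KRT6A from -0.224 to 0.0397. Camera adjusted p of lists that turned were, with no filter, 0.947 (cytokines), 0.845 (antimicrobial), 0.979 (EGFR) and 0.745 (fibroblast). The fibroblast list gave 0.907 with a CPM minimum and 0.982 with the replicate block. After GC and length correction chemokines and antimicrobial genes gave 0.896, cytokines 0.952 and fibroblast markers 0.954, each 0.956 with an estimated correlation. With the replicate block and GC correction these were 0.923 (chemokines, cytokines), 0.947 (antimicrobial) and 0.926 (fibroblast). Without genes carrying either 7-mer EGFR gave 0.881 and NRF2 targets 0.807. With each library left out the lists that turned in at least 1 such fit had adjusted p of 0.481 to 0.945 (chemokines), 0.597 to 0.998 (cytokines), 0.426 to 0.998 (antimicrobial), 0.355 to 0.941 (immediate early), 0.426 to 0.995 (apoptosis), 0.0487 to 0.998 (mitochondrial, the lowest being in its own direction) and 0.597 to 0.984 (p53).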

Other observations

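The tests of list calls after corrections, of the limits of list correlations and of other splits were chosen after the related results were seen; those of rearranged 7-mers and of zinc finger genes with and without a site were fixed beforehand. Genes named in the next 2 paragraphs outside the fixed rule were chosen after their values were seen.

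The cyclooxygenase PTGS1 fell by 1.87 (SE 0.16, edgeR adjusted p = 0.00506), from 24.2 to 6.63 mean CPM, and the prostaglandin E synthase PTGES by 1.93 (SE 0.17, edgeR adjusted p = 0.00506), from 44.9 to 11.7 mean CPM. The Notch ligand DLL1 (-1.92, edgeR adjusted p = 0.0135) and the sterol transporter ABCG1 (-1.90, edgeR adjusted p = 0.0105) fell as well. PTGS1, PTGES, DLL1 and ABCG1 carry neither GTATAAA in the 3′ UTR nor TCGGAGA in the coding sequence or 3′ UTR. The ferritin pseudogenes FTH1P8 (-1.28), FTH1P7 (-1.12) and FTH1P10 (-0.96) fell together with FTH1, and reads shared between them cannot be separated in this table.

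Of 440 tested genes with ZNF symbols and a searched 3′ UTR, 272 (61.8%) had a positive log2 fold change, with a median of 0.126, against 5897 (48.6%) and a median of -0.01 over all 12137 searched genes. This group was chosen after its values were seen and was not tested as a set. By single genes 7 rose and 2 fell.

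Of 10 splits of the 6 libraries into 3 and 3, the real one included, 1 gave 226 changed genes or more, the real one itself (highest other 10), and 1 gave 10 lists or more, again the real one (highest other 6). For the 7-mers below, the real split alone, 1 of 10, had an absolute z as large, for GTATAAA 15.2 (highest other 10.9) and for TCGGAGA 12.9 (highest other 9.0). Other 7-mers also had large z values in other splits, such as 9.76 in coding sequences and -7.12 in 3′ UTRs. With 10 splits the share cannot fall under 0.05.

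Fallen genes often carried GTATAAA in the 3′ UTR: 45 of 115 fallen genes searched (39.1%), against 15.8% of the others, and its z of -15.2 was the lowest of 16314 7-mers. The median log2 fold change was -0.084 with 1 copy, -0.178 with 2 and -0.273 with 3 or more, against 0.006 without, and -0.014 with copies in the coding sequence alone. Unlike the z, these medians and percentages were not adjusted for 3′ UTR length. Genes with longer transcripts tended to be lower in siKMT2C (Spearman correlation -0.152), so a part played by length in the gradient with copies was not separated. GTATAAA was picked as the lowest, so rearrangements of its bases had to lie above it and only the gap is a test. The most extreme of 104 had a z of -4.79. With the log2 fold change corrected for GC and length, GTATAAA kept a z of -13.2. These values argue against a trend with base composition as the whole cause. Picked on odd-numbered chromosomes and X alone, GTATAAA also ranked 1 on the others (z -10.4). Seed-type off-target repression by the KMT2C siRNA is a candidate explanation and stays open: its sequence is not known here, and another cause acting through this 7-mer would give the same association. Loss of KMT2C itself stays open as well and was not tested, since the siKMT2C libraries carry both the loss and the reagent.

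Risen genes often carried TCGGAGA in the coding sequence or 3′ UTR: 29 of 95 risen genes searched (30.5%), against 9.4% of the others (SLC7A2, TPM4, NOLC1 and SETD7 among them). Its z of 12.89 was second to that of the overlapping CGGAGAA (12.99), and in 3′ UTRs alone its z was 6.92, where GGAGAAT had the highest (9.57). The median log2 fold change, not adjusted for region length, was 0.048 with TCGGAGA and -0.016 without. Since TCGGAGA was picked for its high z, only the gap to its rearrangements is a test, and the most extreme of 419 had 6.61. With the log2 fold change corrected for GC and length, its z was 11.84. This argues against GC content, or these bases in any order, as the whole cause. A trend shared with 7-mers of other bases, such as GGAGAAA (11.39), was not tested and stays open. Picked on odd-numbered chromosomes and X alone, CGGAGAA came first and ranked 2 on the others (z 8.4). A candidate explanation is that the control siRNA represses such genes in siNC, so that they look higher in siKMT2C. It stays open, since that sequence is not known here either, and neither it nor an effect of KMT2C loss was tested with a further siRNA. For zinc finger genes the same explanation was not borne out and stays open: those with TCGGAGA had a median 0.027 below those without (with minus without -0.027, permutation p = 0.709, 55 and 385 genes), and shorter matches were not examined.

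Of the called lists, S phase, unfolded protein response, interferon, cholesterol, G2/M and epidermal transcription factors kept their calls after GC and length correction (largest camera adjusted p 0.00291). They also kept them without genes carrying either 7-mer (largest camera adjusted p 0.0113). Both p-values use the preset correlation, and with GC correction and an estimated correlation only S phase was called. In the order given, medians over all members were 0.40, 0.47, -0.36, 0.29, 0.21 and -0.25. After GC and length correction they were 0.41, 0.48, -0.33, 0.28, 0.16 and -0.25. Members without a site had medians of 0.41, 0.47, -0.38, 0.29, 0.21 and -0.25. These medians argue against the GC trend, and against GTATAAA or TCGGAGA sites in the members themselves, as the whole cause. Genes were not dropped for other 7-mers with a high z in coding sequence or 3′ UTR, such as GGAGAAA (11.39) and GGAGAAT (11.27). Other sites in the members therefore stay open. Co-expression of members apart from the groups is argued against for S phase (camera adjusted p = 0.0392 with an estimated correlation, 0.039 with GC correction too) and stays open for the other 5. The S phase estimate was -0.017. It also rests on 4 residual degrees of freedom, and its upper 95% limit of 0.0558 lies above the preset 0.01. The unfolded protein response, G2/M and interferon lists had estimated correlations of 0.102, 0.154 and 0.362 (smallest adjusted p with them 0.127). Cholesterol and epidermal transcription factors had -0.00602 and 0.00399, under the preset 0.01, so their calls (adjusted p 0.121 apiece) did not end through a higher measured correlation; that test rests on 4 residual degrees of freedom, and the upper 95% limits of these correlations were 0.253 and 0.436. With fry the S phase, unfolded protein response, cholesterol and epidermal transcription factor lists kept their calls (adjusted p 0.00013, 0.0096, 0.0374 and 0.0096). The ribosomal protein shift may be a GC or transcript length effect. Its median went from 0.0977 (quartiles 0.044 and 0.198) to 0.0285 (quartiles -0.0275 and 0.147) after correction for both. That correction takes out both trends together, so GC and length cannot be told apart here. Without genes carrying either 7-mer or not searched, the desmosome, lipid barrier, RNA interference and ribosomal protein lists were not called (adjusted p 0.112, 0.18, 0.799 and 0.0557). Their medians were -0.316, -0.0539, -0.364 and 0.0977 over all members and -0.248, -0.029, -0.207 and 0.093 over those searched without a site. Members with a site had medians of -0.382, -0.729, -0.817 and 0.0977 (8, 3, 5 and 8 members), so only the ribosomal medians were nearly alike. Fewer members were then tested (12, 10, 7 and 38, against 20, 13, 12 and 62), so a part played by sites stays open. In the ribosomal list only 46 of the 62 members were searched, so many were dropped for want of a searched 3′ UTR. Effects of KMT2C loss and indirect effects of either siRNA on the S phase genes cannot be separated with the libraries used here.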
